A study of Mus musculus with 16 samples.

How the data were processed

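Total RNA from cultured primary smooth muscle cells of the mouse aorta was sequenced in 16 libraries, 4 in each of 4 groups formed by genotype and medium. Per the labels' protocols, the cells came from collagenase-digested aortas of mice that lack Arg1 in the red blood cell lineage, made by crossing floxed Arg1 mice with mice carrying Cre recombinase under the erythropoietin receptor gene (KO), and of their littermates (WT). Control cultures stayed in Dulbecco's modified Eagle medium (DMEM) with 10% fetal bovine serum. The other cultures were moved for 10 days to DIAM, which is DMEM with dexamethasone (0.1 µM), insulin (1 µM) and L-ascorbic acid (50 µg/mL). Whether DIAM also held serum is not given in the sources used here. Libraries were made with an unstranded TruSeq kit and depletion of ribosomal RNA. The series' design text speaks of 4 biological replicates per group while the library protocol speaks of triplicates; 4 libraries per group were analysed. All libraries carry the same batch label and the label male.

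The authors' deposited table gives 1 line for each of 20581 genes, of which 19293 carry a gene symbol, and every gene has a value above 0 in at least 9 of the 16 libraries. Per the submitters' processing notes, FastQC, Salmon 1.9.0, DESeq2 1.46.0 and R 4.4.2 were used with the mouse genome build GRCm39. Per the labels the library columns hold TPM, but each column sums to between 37221192 and 47626331, far above the fixed sum that TPM has and different in each library, and the values are not whole, so the deposited values were treated as estimated counts per gene. The same table holds the authors' log2 fold changes and adjusted p-values for 4 comparisons: DIAM against DMEM in WT cells, KO against WT in each medium, and the interaction of genotype and medium. Values of the authors' own for DIAM against DMEM in KO cells were not used here. No genome coordinates are given, because the reference annotation at hand was of another build.

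The estimated counts were rounded to whole numbers. Genes were kept when they reached at least 1 CPM, the count scaled to the library total, in at least 4 of the 16 libraries, which left 14217 genes and at least 99.83% of each library's counts. Before the data were examined, limma on log2(TPM + 1) had been planned, with a count test in its place if the table held counts. The main test was therefore the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with trimmed-mean (TMM) scaling, robust dispersion estimates and 1 model over the 4 groups with 12 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene counted as changed at an adjusted p under 0.05. Levels are TMM-scaled CPM, as mean ± SD over the 4 libraries of a group. Log2 fold changes carry an approximate standard error (SE). It was back-calculated as the absolute log2 fold change divided by the square root of the test's F statistic, and is least reliable where a group lies near 0. For genes below the filter, counts and unscaled CPM are given. The interaction term tests whether the change from DMEM to DIAM differs between genotypes.

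Fixed at the same time were 20 gene lists (pathways of glucocorticoid response, lipid handling, cholesterol, matrix, contraction, inflammation, stress, growth and arginine metabolism) and 10 lists of markers of other cell types or of library quality. Each list was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of its kind within a comparison. For each list the members past the genewise threshold were counted, over all genes and adjusted over the list alone. Lists with fewer than 3 measured genes were not given to camera. Genes to be named were also chosen by a rule fixed in advance. It takes the 8 largest rises and 8 largest falls in each comparison of 2 groups (5 and 5 for the interaction) among changed genes at 5 CPM or more whose groups did not overlap, without predicted genes. It adds Arg1, Arg2, Odc1 and Epor, up to 4 genes of smallest p from each list, the most abundant members where fewer than 2 pass, the same genes in the other genotype or medium and, where fewer than 10 genes passed, those that passed and the 5 of smallest p among the rest. Some genes that the rule takes are not reported here. Any gene outside the rule is said to have been chosen after its values were seen.

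The alternatives tried were pseudocounts of 0.1 and 5 with limma on log2 CPM, no filter, a filter at 5 CPM, median-ratio scaling, quantile normalization, fits of only the 2 groups compared, a replicate block, a fit without trend and robust estimates, library weights, a minimum absolute log2 fold change of 1, the authors' deposited adjusted p-values, and leaving out each library in turn. Chosen after the data were seen were DESeq2 1.42.0 on the same counts, limma on log2(CPM + 1), a Schwann or neuronal score or a mesothelial score as a covariate, and leaving out both libraries at the ends of the second principal component. The code was tested on simulated counts for the 14217 genes with known changes. In the simulated comparison of KO with WT in DMEM the test recovered 64.18% of genes changed 1.5-fold and 79.1% of those changed 2-fold. For KO against WT in DIAM it recovered 67.16% and 79.1%, and for the interaction 53.73% and 68.66%. In each comparison 67 genes were changed at each of these folds. Counts were drawn independently, without differences shared among genes of a sample, so the shares do not measure the power in the real data. Replicates of a group differed well beyond counting noise, with a chi-square per degree of freedom from 10.22 to 62.13, so no libraries were merged. The kit does not mark strand, so reads of overlapping and antisense genes cannot be told apart. Counts of genes with close copies, such as Serpina3m, Orm1, Ces1d and Gstm1, depend on how the counting shared reads among the copies.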

Results

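Gene expression was measured by total RNA sequencing in primary aortic smooth muscle cells from WT mice and from KO mice, whose red blood cell lineage had lost Arg1, kept in DMEM or moved for 10 days to DIAM, a medium meant to make the cells accumulate lipid. Each of the 4 groups had 4 libraries. Total counts were 42034401 ± 4149623 in WT cells in DMEM (mean ± SD, n = 4), 38840698 ± 1709605 in KO cells in DMEM, 39507793 ± 2540152 in WT cells in DIAM and 39590213 ± 2053677 in KO cells in DIAM. The first principal component held 75.1% of the variance and the second 6.72%. Mitochondrially encoded transcripts took 1.5 ± 0.13%, 1.56 ± 0.05%, 1.82 ± 0.084% and 1.98 ± 0.074% of the counts in the same order of groups.

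Arg1 (ENSMUSG00000019987), the arginase removed from the red blood cell lineage of KO mice, was close to absent from the smooth muscle cells. Its counts were 3, 4, 3 and 3 in the WT libraries 1 to 4 in DMEM, 12, 22, 2 and 49 in the KO libraries in DMEM, 1, 9, 0 and 5 in the WT libraries in DIAM, and 3, 4, 2 and 1 in the KO libraries in DIAM. The count of 0 in WT library 3 in DIAM allows up to 0.0756 CPM, from counting error only. Arg1 lay below the filter and was not tested. Smooth muscle cells are not the cells in which Arg1 was removed, so these counts say nothing about whether the genotype labels are right. Arg2, the mitochondrial arginase, averaged 4.75 ± 3.4 counts in WT and 5.25 ± 0.957 in KO cells in DMEM (n = 4 each), and 2.25 ± 2.22 and 1.75 ± 1.26 in DIAM. Epor, the erythropoietin receptor, averaged 15.2 ± 7.93, 10.0 ± 5.35, 15 ± 6.16 and 10.8 ± 6.99 counts in the same groups. Neither was tested. Of 11 erythroid marker genes 1 was tested, Alas2, the first enzyme of erythroid heme synthesis, which rose with DIAM from 0.0279 ± 0.0263 to 1.83 ± 0.958 CPM in WT cells (adjusted p = 2.03e-05, edgeR) and from 0.131 ± 0.0678 to 3.89 ± 2.86 CPM in KO cells (adjusted p = 1.03e-05). Odc1, the ornithine decarboxylase that starts polyamine synthesis, fell in DIAM from 203 ± 13.7 to 125 ± 5.8 CPM in WT cells (adjusted p = 5.31e-07) and from 194 ± 20.5 to 111 ± 6.42 CPM in KO cells (adjusted p = 9.27e-08, edgeR).

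The first comparison asked what DIAM changed in WT cells. Of the gene lists, 22 of 24 glucocorticoid response and 21 of 21 adipocyte genes rose, while 19 of 20 cholesterol synthesis, 21 of 30 matrix and 22 of 25 cell cycle genes fell. With an estimated correlation the glucocorticoid list kept its call (adjusted p = 7.42e-06), and the adipocyte (adjusted p = 0.0949), cholesterol synthesis (0.0989), matrix (0.329) and cell cycle (0.415) lists did not. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 23.3-fold, from 21.7 ± 1.03 to 506 ± 53.3 CPM (n = 4). Fabp4, the fatty acid binding protein of adipocytes, rose 18.1-fold, from 73.2 ± 5.69 to 1322 ± 205 CPM. Sqle, the squalene epoxidase of cholesterol synthesis, fell from 241 ± 23.5 to 56.2 ± 1.43 CPM, and Thbs1, the matrix protein thrombospondin 1, from 10610 ± 904 to 1592 ± 348 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7839 of 14217 genes changed (55.1%), 3929 upward and 3910 downward, or 3287 upward and 4886 downward with quantile normalization. With a log2 fold change of at least 1 in either direction the number was 2140, of which 1292 rose.

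Among the 8 largest rises in WT cells were those of Serpina3m, C7, Cldn11, Zbtb16, Orm1, Thrsp and Fam107a. Serpina3m, a serine protease inhibitor, rose from 0.0618 ± 0.0631 to 301 ± 93.9 CPM, a log2 fold change of 12.24 ± 0.38 (SE). The complement component C7 rose from 0.490 ± 0.235 to 330 ± 55.8 CPM. Zbtb16, a transcription factor induced by glucocorticoids, rose by 9.24 ± 0.22 on the log2 scale. The 8 largest falls were those of Fcrl2, Sost, Nell2, Sfrp4, Mmp12, Scg2, Grik1 and Gas2. Fcrl2 had a log2 fold change of -8.92 ± 0.50, from 51.5 ± 16.9 to 0.101 ± 0.0754 CPM, and Sfrp4, a secreted Wnt antagonist, fell from 216 ± 32.8 to 3.41 ± 1.12 CPM.

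Of the 24 glucocorticoid response genes, 22 rose and 1 fell in WT cells. Besides Fkbp5 and Zbtb16, the kinase Sgk1 rose from 31.3 ± 2.42 to 415 ± 26.1 CPM and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, from 25.9 ± 3.11 to 348 ± 12 CPM. The member that fell was Nr3c1, the glucocorticoid receptor itself, from 168 ± 10.2 to 115 ± 14.3 CPM, and it was chosen for naming after its values were seen. This list kept its call with an estimated correlation, with adjusted p = 7.42e-06. All 21 adipocyte and lipid storage genes tested rose, among them the adipokine Retn, from 0.218 ± 0.118 to 37.7 ± 9.04 CPM, and the triglyceride lipase Pnpla2, from 32.0 ± 1.37 to 353 ± 90.7 CPM (camera adjusted p = 4.35e-26; adjusted p = 0.0949 with an estimated correlation). Of 15 fatty acid synthesis genes 9 rose and 5 fell (camera adjusted p = 0.0545). Scd1, the stearoyl-CoA desaturase, rose from 432 ± 28.5 to 5146 ± 1230 CPM, whereas Fads1, a desaturase of polyunsaturated fatty acids, fell from 268 ± 14.3 to 151 ± 7.95 CPM. Of 18 fatty acid oxidation genes 14 rose and 1 fell, with Acadm, the medium-chain acyl-CoA dehydrogenase, rising from 47.1 ± 2.34 to 128 ± 18.7 CPM (adjusted p = 0.329 with an estimated correlation). Of 20 genes of cholesterol synthesis and uptake 19 fell, among them Fdps, from 188 ± 15.7 to 65.8 ± 2.5 CPM (adjusted p = 0.0989 with an estimated correlation). Of 17 genes of cholesterol efflux and scavenger receptors 10 rose and 2 fell, including the liver X receptor gene Nr1h3, from 6.97 ± 0.552 to 29.3 ± 1.5 CPM, and the fatty acid transporter Cd36, from 12.8 ± 2.76 to 214 ± 63.2 CPM (adjusted p = 0.376 with an estimated correlation).

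Of 18 contractile smooth muscle genes 9 fell and 3 rose in WT cells. Tagln (transgelin) fell from 1067 ± 173 to 432 ± 68.6 CPM and Cnn1 (calponin 1) from 83.9 ± 10.5 to 16.1 ± 6.37 CPM, whereas Myocd, which encodes the smooth muscle coactivator myocardin and was named after its values were seen, rose from 3.92 ± 1.34 to 10.0 ± 1.91 CPM (adjusted p = 0.614 with an estimated correlation). Of 30 collagen and matrix genes 21 fell and 8 rose, with Col8a1 falling from 3205 ± 160 to 842 ± 76.3 CPM (adjusted p = 0.329 with an estimated correlation). Of 17 TGF-beta response genes 11 fell and 1 rose, and Smad3, a signal transducer of TGF-beta, fell from 67.8 ± 1.78 to 23.7 ± 2.15 CPM (adjusted p = 0.107 with an estimated correlation). Of 25 cell cycle genes 22 fell and 1 rose. Ccna2 (cyclin A2) fell from 14.0 ± 1.37 to 6.78 ± 1.31 CPM, and the member that rose was the ribonucleotide reductase subunit Rrm2, from 28.9 ± 1.81 to 63.6 ± 10.3 CPM (adjusted p = 0.415 with an estimated correlation). Of 20 genes of arginine, polyamine and nitric oxide metabolism 11 fell and 5 rose, and Ddah1, which breaks down methylated arginines, fell from 261 ± 21.8 to 104 ± 7.69 CPM (adjusted p = 0.368 with an estimated correlation).

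The other lists did not pass camera in WT cells. Members that rose and fell numbered 4 and 9 of 17 osteochondrogenic genes, 4 and 7 of 16 inflammatory genes, 6 and 9 of 19 matrix proteases and inhibitors, and 9 and 1 of 20 interferon-stimulated genes. They numbered 3 and 12 of 18 genes of the unfolded protein and integrated stress responses, 10 and 3 of 22 lysosome and autophagy genes, 10 and 2 of 19 oxidative stress defence genes, 11 and 4 of 22 insulin and IGF genes, and 6 and 3 of 14 genes of macrophage-like foam cells. Il6 fell from 19.6 ± 4.84 to 2.30 ± 0.177 CPM, Cxcl12 from 4756 ± 375 to 1988 ± 143 CPM and Bmp4 from 258 ± 27.9 to 35.8 ± 8.35 CPM. Adjusted over the list alone, 10 contractile, 22 matrix and 8 inflammatory genes fell and 11 lysosomal and 12 insulin genes rose, with the other counts unchanged.

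Markers of other cells also moved with DIAM in WT cells. Of 12 fibroblast markers 10 rose and 2 fell (adjusted p = 0.00506 with an estimated correlation), with Dcn (decorin) rising from 421 ± 77 to 840 ± 125 CPM and Pdgfra from 199 ± 32.1 to 330 ± 43.1 CPM. All 6 measured markers of perivascular adipocytes rose (adjusted p = 0.0153 with an estimated correlation), and 5 of these 6 are also in the adipocyte list. Of 7 Schwann or neuronal markers 4 rose and 2 fell. The glial transcription factor Sox10 rose from 4.47 ± 2.85 to 45.7 ± 18.4 CPM. Members that rose and fell numbered 6 and 1 of 12 endothelial, 3 and 4 of 14 leukocyte, 2 and 0 of 8 mesothelial, 1 and 1 of 2 cardiac or skeletal and 8 and 1 of 13 mitochondrially encoded genes. The marker genes Dcn, Pdgfra and Sox10 were chosen after their values were seen. The numbers of changed genes moved by less than 1.5 times without any single library.

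The second comparison was of DIAM with DMEM in KO cells, where 22 of 24 glucocorticoid response and 21 of 21 adipocyte genes rose and 19 of 20 cholesterol synthesis, 22 of 30 matrix and 24 of 25 cell cycle genes fell. With an estimated correlation the glucocorticoid list kept its call (adjusted p = 2.78e-05), and the adipocyte (adjusted p = 0.0619), cholesterol synthesis (0.119), matrix (0.152) and cell cycle (0.24) lists did not. Fkbp5 rose 28.9-fold, from 21.0 ± 1.51 to 606 ± 19.4 CPM, Fabp4 24-fold, from 73.1 ± 15.6 to 1756 ± 296 CPM, and Scd1 21.3-fold, from 393 ± 50.3 to 8389 ± 1080 CPM. Sqle fell from 220 ± 46.6 to 53.9 ± 3.08 CPM, Thbs1 from 10300 ± 785 to 1675 ± 44.1 CPM and Plk1, a kinase of mitosis, from 7.0 ± 0.765 to 2.23 ± 0.257 CPM. By edgeR's test 8623 of 14217 genes changed (60.7%), 4243 upward and 4380 downward (3662 and 5107 with quantile normalization), and 2432 did so by at least 1 on the log2 scale. Among the largest rises were those of Serpina3m, Cldn11, Thrsp, Zbtb16, C7, Cidec and Car3. Serpina3m had 3 counts over the 4 KO libraries in DMEM and reached 175 ± 37.3 CPM in DIAM, and Cidec, a lipid droplet protein, rose from 0.442 ± 0.321 to 248 ± 43.3 CPM. Among the largest falls were those of Fcrl2, Sost, Slc5a7, Nell2, Sfrp4, Mmp13 and Grik1, with Mmp13, a collagenase, falling from 70.4 ± 45.6 to 1.09 ± 0.4 CPM.

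In KO cells 22 of 24 glucocorticoid response genes rose and 1 fell (adjusted p = 2.78e-05 with an estimated correlation), and all 21 adipocyte genes rose (adjusted p = 0.0619 with an estimated correlation). Of 15 fatty acid synthesis genes 10 rose and 4 fell (camera adjusted p = 0.000401; adjusted p = 0.288 with an estimated correlation), of 18 fatty acid oxidation genes 14 rose and 1 fell (adjusted p = 0.119 with an estimated correlation), and of 20 cholesterol synthesis genes 19 fell and 1 rose (adjusted p = 0.119 with an estimated correlation). Col8a1 fell from 3089 ± 232 to 643 ± 73.3 CPM, among 22 matrix genes that fell and 6 that rose of 30 (adjusted p = 0.152 with an estimated correlation). Of 25 cell cycle genes 24 fell and 1 rose (adjusted p = 0.24 with an estimated correlation), and of 17 TGF-beta response genes 9 fell and 1 rose (adjusted p = 0.119 with an estimated correlation). Members that rose and fell numbered 4 and 10 of 20 arginine and polyamine genes (adjusted p = 0.21 with an estimated correlation). Camera also called 10 and 3 of 17 cholesterol efflux, 3 and 12 of 18 stress response, 10 and 3 of 19 oxidative stress and 13 and 4 of 22 insulin genes, each at adjusted p = 0.288 with an estimated correlation. Lists that did not pass camera had 4 and 8 of 18 contractile, 4 and 11 of 17 osteochondrogenic, 4 and 7 of 16 inflammatory, 6 and 13 of 19 protease, 6 and 3 of 20 interferon, 8 and 6 of 22 lysosomal and 4 and 7 of 14 foam cell genes that rose and fell. The lysosomal list had a median log2 fold change of 0.04 and a mean of -0.06. Adjusted over the list alone, 7 matrix and 4 stress response genes rose and 12 osteochondrogenic genes fell, with the other counts unchanged.

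Among markers in KO cells, 10 fibroblast markers rose and 2 fell of 12 (adjusted p = 0.00652 with an estimated correlation) and all 6 perivascular adipocyte markers rose (adjusted p = 0.0146 with an estimated correlation). Of 14 leukocyte markers 8 fell, and 9 of 13 mitochondrially encoded genes rose and 1 fell (adjusted p = 0.539 with an estimated correlation). Members that rose and fell numbered 6 and 2 of 12 endothelial, 2 and 3 of 7 Schwann or neuronal, 2 and 0 of 8 mesothelial and 1 and 1 of 2 cardiac or skeletal genes. Sox10 was at 5.09 ± 5.66 CPM in DMEM and 11.7 ± 6.88 CPM in DIAM (adjusted p = 0.151, edgeR), and it passed without KO library 2 in DMEM, at a log2 fold change of 2.35. Xist fell from 224 ± 82.8 to 113 ± 8.19 CPM (adjusted p = 0.00254, edgeR). Sox10 and Xist were named after their values were seen.

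The medium responses of the genotypes, which share no libraries, were set side by side across genes, which are not independent replicates. Of the genes that rose, 3320 did so in both genotypes, where independent lists would share 1173, and of the genes that fell 3281 did, where independent lists would share 1205. Another 7 genes changed in opposite directions. Across the 14217 genes the log2 fold changes had a Pearson correlation of 0.934, a Spearman correlation of 0.882 and a slope of KO on WT through the origin of 0.969. Without the filter on low counts the slope was 0.839. Error in the WT fold changes lowers such a slope, so neither value shows a weaker response in KO cells.

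**Figure D1:**
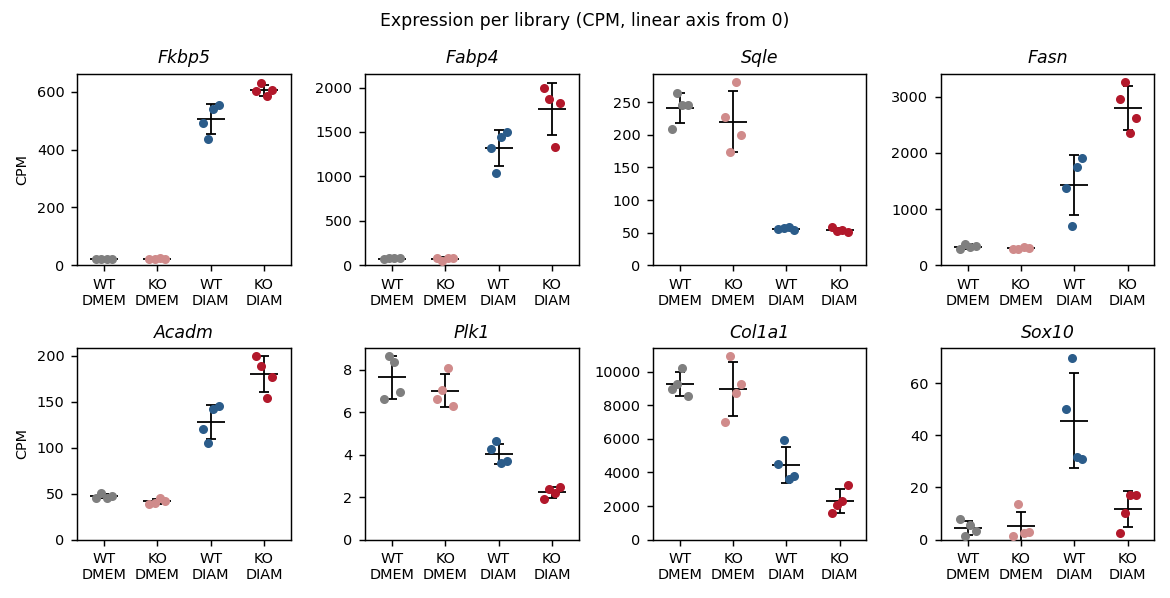
CPM (TMM-scaled, linear axes from 0) of 8 genes in each of the 16 libraries by genotype and medium, with 1 dot per library and a bar and whiskers for mean ± SD over 4 libraries. Fkbp5 and Fabp4 rose and Sqle fell with DIAM in both genotypes, and Fasn in DIAM was at 1434 ± 536 CPM in WT and 2800 ± 394 CPM in KO cells.

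KO and WT cells were next compared in DMEM, which asks whether the genotype matters without the lipid accumulation medium. No gene passed edgeR's test. The gene of smallest p was Zdhhc18 (ENSMUSG00000037553), a palmitoyltransferase gene, at 26.7 ± 1.84 CPM in WT and 38.2 ± 1.73 CPM in KO cells (log2 fold change 0.51 ± 0.09, adjusted p = 0.46). Next came Gm4202, Igsf9b, Kank3 and H2bc23, at adjusted p = 1 each. Kank3 was at 2.16 ± 0.372 CPM in WT and 3.44 ± 0.572 CPM in KO cells, and Igsf9b at 15.8 ± 0.902 and 11.5 ± 1.17 CPM. The count of 0 by edgeR stood beside 438 genes at an unadjusted p under 0.05, where 711 would be expected by chance, and limma on log2(CPM + 1) also gave 0. DESeq2 on the same counts gave 1 gene, and the authors' deposited table gives 2, Zdhhc18 (log2 fold change 0.51, adjusted p = 3.51e-07) and Lat2 (0.97, adjusted p = 0.0122), which was named after its values were seen. Without KO library 1 in DMEM edgeR called 2 genes.

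Camera placed 7 of the 20 gene lists past its threshold in DMEM, none of them with an estimated correlation, where the smallest adjusted p was 0.631. Lists lower in KO cells were cholesterol synthesis (median log2 fold change -0.11, camera adjusted p = 1.77e-06), matrix (-0.06, 0.00313), cell cycle (-0.09, 0.0226), arginine and polyamine genes (-0.06, 0.042) and TGF-beta response (-0.08, 0.0472). Lists higher in KO cells were macrophage-like foam cell genes (0.27, 0.000235) and interferon-stimulated genes (0.11, 0.00235). Among markers, the leukocyte list was higher in KO cells (median 0.31, camera adjusted p = 9.05e-05), as were mesothelial (0.57, 0.0309) and mitochondrially encoded genes (0.07, 0.0324), each at adjusted p = 0.702 with an estimated correlation. Leukocyte transcripts were present in DMEM. C1qa, named after its values were seen, was at 77.5 ± 23.2 CPM (unscaled) in WT and 95 ± 33.3 CPM in KO cells. Of the leukocyte markers 2, Adgre1 and Itgam, are also in the foam cell list. Which cells the foam cell list followed was not tested. Adjusted over the list alone, no list had a member that passed. Median and mean differed in sign for glucocorticoid response, fatty acid oxidation, cholesterol efflux and protease genes, of which none passed camera.

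In DIAM, 9 of 21 adipocyte, 7 of 15 fatty acid synthesis and 9 of 18 fatty acid oxidation genes were higher in KO than in WT cells, and 18 of 25 cell cycle and 11 of 30 matrix genes were lower. None of these 5 lists was called with an estimated correlation (adjusted p = 0.124 to 0.127). Fasn, the fatty acid synthase, was at 1434 ± 536 CPM in WT and 2800 ± 394 CPM in KO cells (1.95-fold; adjusted p = 0.0197, edgeR), and Acadm at 128 ± 18.7 and 180 ± 19.5 CPM (1.4-fold; adjusted p = 0.012). Plk1 was at 4.04 ± 0.48 CPM in WT and 2.23 ± 0.257 CPM in KO cells, Col1a1, a chain of type I collagen, at 4466 ± 1070 and 2309 ± 696 CPM, and Tnc (tenascin C) at 226 ± 69.7 and 91.3 ± 32 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1191 of 14217 genes differed (8.38%), 487 higher and 704 lower in KO cells. The smallest adjusted p was 0.00483, that of Kif23 (ENSMUSG00000032254), a kinesin of cell division named after its values were seen, at 3.11 ± 0.775 CPM in WT and 0.687 ± 0.235 CPM in KO cells. With a log2 fold change of at least 1 in either direction 167 genes remained, 14 of them higher.

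Among the 8 largest rises in KO cells in DIAM were those of Kcnk3, Thrsp, Ogn, Sorl1, Ces1d, Fasn and Car3. The potassium channel gene Kcnk3 had a log2 fold change of 1.24 ± 0.31, from 7.92 ± 3.62 to 18.7 ± 4.15 CPM, and the lipogenic regulator Thrsp one of 1.12 ± 0.29. The 8 largest falls were of Epha5, Gria1, Kcnh2, Tspan15, Artn, Gap43, B3galt5 and Ntm. Epha5, an ephrin receptor, had a log2 fold change of -2.68 ± 0.75, Gria1, a glutamate receptor subunit, one of -2.65 ± 0.61, and Gap43, a growth cone protein, went from 37.8 ± 23.7 CPM in WT to 9.06 ± 5.74 CPM in KO cells. Gria1 was at 14.2 CPM in WT library 2 and at 3.43 to 4.79 CPM in the other WT libraries in DIAM. With each of the 8 libraries in DIAM left out in turn, Epha5 lost its call 6 times, Tspan15, Gap43 and B3galt5 5 times and Kcnh2 4 times. Gria1 lost it 3 times, Artn 1 time and Ntm 0 times. Among the rises, Ces1d lost it 6 times, Sorl1 4, Kcnk3, Thrsp and Fasn 3, Car3 1 and Ogn 0.

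Of 21 adipocyte genes 9 were higher in KO cells in DIAM, or 19 adjusted over the list alone, among them Agpat2, from 121 ± 26.1 to 186 ± 26.8 CPM (adjusted p = 0.127 with an estimated correlation). Of 15 fatty acid synthesis genes 7 rose, or 11 adjusted over the list alone, with Scd1 at 5146 ± 1230 and 8389 ± 1080 CPM, and of 18 fatty acid oxidation genes 9 rose, or 10 adjusted over the list alone, with Cpt2 at 38.7 ± 4.67 and 56.6 ± 7.58 CPM (adjusted p = 0.124 with an estimated correlation for both lists). Of 25 cell cycle genes 18 fell, or 21 adjusted over the list alone, including Ube2c, from 5.33 ± 1.56 to 2.85 ± 0.426 CPM (adjusted p = 0.124 with an estimated correlation). Of 30 matrix genes 11 fell, or 16 adjusted over the list alone, and of 19 proteases and inhibitors 5 fell, or 8 with 1 rise adjusted over the list alone, including the inhibitor Timp1, from 352 ± 84.1 to 217 ± 12.7 CPM (adjusted p = 0.124 with an estimated correlation for both lists). Of 20 arginine, polyamine and nitric oxide genes 4 fell, or 12 with 1 rise adjusted over the list alone (adjusted p = 0.124 with an estimated correlation). These were the proline synthesis enzymes Aldh18a1 and Pycr1, Ddah1, and Ass1, the argininosuccinate synthase, which went from 106 ± 16.2 to 77.1 ± 4.08 CPM. When each library in DIAM was left out in turn, Pycr1 lost its call 5 times, Ddah1 and Ass1 4 times each and Aldh18a1 1 time.

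In the insulin and IGF list 5 genes rose and 1 fell of 22, or 9 and 2 adjusted over the list alone, with the insulin receptor gene Insr at 69.7 ± 8.75 and 92.5 ± 5.82 CPM (adjusted p = 0.133 with an estimated correlation). Camera also called glucocorticoid response (5 rose and 1 fell of 24; adjusted p = 0.274 with an estimated correlation), oxidative stress defence (3 and 1 of 19, with catalase, Cat, at 171 ± 25.2 and 237 ± 20.9 CPM; 0.285), stress responses (0 and 3 of 18; 0.257), interferon-stimulated genes, where 20 of 20 did not pass (0.608), and contractile genes, where 18 of 18 did not pass (0.568) and the smooth muscle myosin Myh11 was at 101 ± 35.9 and 158 ± 44.2 CPM (adjusted p = 0.167). Adjusted over the list alone, 6 glucocorticoid genes rose and 2 fell, 4 oxidative stress genes rose and 2 fell, and 6 stress response genes fell. Members that rose and fell in lists that did not pass camera numbered 1 and 1 of 17 cholesterol efflux genes, 0 and 3 of 17 osteochondrogenic, 1 and 2 of 16 inflammatory, 1 and 0 of 22 lysosomal, 0 and 1 of 14 foam cell and 1 and 2 of 17 TGF-beta genes. Adjusted over the list alone they numbered 2 and 1 cholesterol efflux, 0 and 4 osteochondrogenic, 2 and 3 inflammatory and 2 and 6 TGF-beta genes, with the lysosomal and foam cell counts unchanged. The cholesterol efflux list had a median log2 fold change of -0.03 and a mean of 0.04. The TGF-beta member Tgfbi went from 60.6 ± 25.3 to 20.2 ± 6.59 CPM. Of 20 cholesterol synthesis genes 20 did not pass, while 2 rose and 3 fell adjusted over the list alone.

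Markers of other cells differed with genotype in DIAM as well. Of 7 Schwann or neuronal markers 3 fell in KO cells, or 5 adjusted over the list alone (camera adjusted p = 7.54e-05; adjusted p = 0.12 with an estimated correlation). These were Cnp, from 35.6 ± 7.07 to 24.9 ± 2.76 CPM, Ncam1, from 34.4 ± 4.52 to 17.1 ± 5.46 CPM, and Tubb3, from 45.7 ± 12.4 to 21.3 ± 5.64 CPM. Sox10 was at 45.7 ± 18.4 CPM in WT and 11.7 ± 6.88 CPM in KO cells (adjusted p = 0.0839). Of 6 perivascular adipocyte markers 2 rose, or 5 adjusted over the list alone, and of 13 mitochondrially encoded genes 1 rose, or 5 adjusted over the list alone (adjusted p = 0.216 with an estimated correlation for both lists). Of 12 fibroblast markers 1 rose, Dpep1, and 2 fell only when adjusted over the list alone. Of 12 endothelial markers Flt1 and Emcn fell. When each library in DIAM was left out in turn, the mitochondrially encoded mt-Nd2 lost its call 7 times, Emcn 6 times and Dpep1 5 times. Cnp lost its call 4 times, Ncam1 3 times and Tubb3 and Flt1 1 time each. Of 14 leukocyte and 8 mesothelial markers 14 and 8 did not pass. All these markers were named after their values were seen.

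The count of 1191 genes in DIAM depended on single libraries and on the test. It was 299 without WT library 1, 316 without WT library 2, 275 without KO library 1 and 178 without KO library 2 in DIAM, and it was 0, with 3674 genes at an unadjusted p under 0.05, when edgeR was fitted to the 8 libraries in DIAM alone. Without both WT library 2 and KO library 1 in DIAM, an exclusion chosen after the data were seen, 16 genes were called, all 16 lower in KO cells. DESeq2 on the same counts gave 1873 genes, of which 1189 were also called by edgeR, and the authors' deposited table gives 1810, of which 1112 were also called here. Of 85 named genes that passed in this comparison, 65 lost the call without at least 1 of them. Fasn lost it without WT library 1 (log2 fold change 0.95), KO library 1 (0.94) or KO library 2 (0.88), and Col1a1 without KO library 2 (-0.91), while Kif23, Acadm, Plk1 and Tnc passed without each library.

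**Figure D2:**
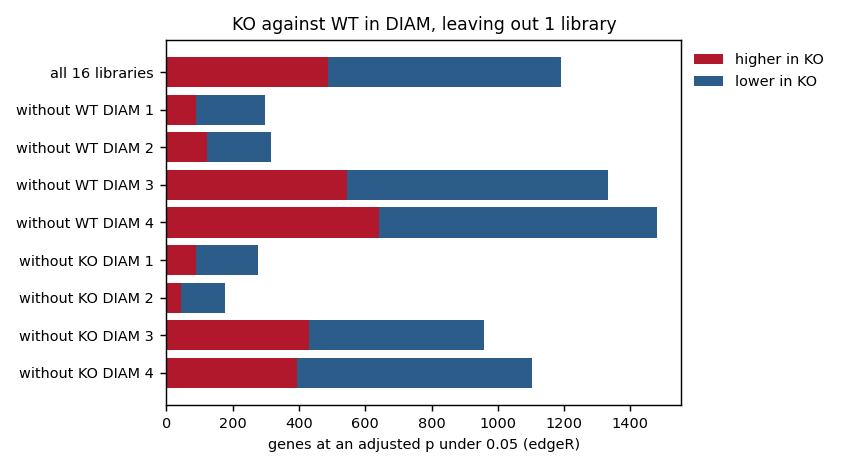
Number of genes (horizontal axis) higher or lower in KO than in WT cells in DIAM at an adjusted p under 0.05 by edgeR, with all 16 libraries and without each of the 8 libraries in DIAM in turn. The number runs from 178 without KO library 2 to 1480 without WT library 4.

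Whether the response to DIAM differed between genotypes was tested as the interaction. No gene passed edgeR's test, with 2255 genes at an unadjusted p under 0.05 where 711 would be expected by chance and a smallest adjusted p of 0.156. That p belonged to Kif23, which fell with DIAM from 5.09 ± 1.18 to 3.11 ± 0.775 CPM in WT and from 5.06 ± 0.735 to 0.687 ± 0.235 CPM in KO cells (interaction log2 fold change -2.17 ± 0.34). Coro1c, Zdhhc18, Tcp11l1 and Ptprn followed at adjusted p = 0.171 each. Coro1c, which encodes the actin-binding coronin 1C, was at 150 ± 6.51 CPM in DMEM and 144 ± 7.2 CPM in DIAM in WT cells, and at 152 ± 5.55 and 113 ± 3.87 CPM in KO cells. The count of 0 by edgeR was 0 with limma on log2(CPM + 1) and 225 with DESeq2, and the authors' deposited table gives 234 genes, led by Kif23 (log2 fold change -2.16, adjusted p = 3.42e-06). Without KO library 1 in DMEM edgeR called 1 gene. In settings chosen after the data were seen, the genes at an unadjusted p under 0.05 numbered 532 with the Schwann or neuronal score as a covariate. They numbered 2294 with the mesothelial score and 1338 without both WT library 2 and KO library 1 in DIAM. The Schwann or neuronal score and genotype go together in DIAM, so the covariate cannot separate them.

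Camera called 12 of the 20 gene lists for the interaction and none with an estimated correlation, where the smallest adjusted p was 0.166. The adipocyte list (median interaction log2 fold change 0.66, camera adjusted p = 1.81e-12) and the fatty acid synthesis list (0.70, 1.42e-09) moved up more in KO cells, and the cell cycle list (-0.49, 5.53e-10) moved down more. Cholesterol efflux genes, which did not pass, had a median of -0.05 and a mean of 0.05. Adjusted over the list alone, 10 of 21 adipocyte, 8 of 15 fatty acid synthesis and 8 of 18 fatty acid oxidation genes passed upward and 7 of 25 cell cycle genes downward. Of 22 insulin and IGF genes 5 passed upward and 1 downward, and in each other gene list at most 2 passed. The Schwann or neuronal markers had a median of -0.94 (camera adjusted p = 0.00156; adjusted p = 0.323 with an estimated correlation).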

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

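The tests of mesothelial markers against sample number and of Arg1 against leukocyte markers, and DESeq2, both marker scores as covariates and the exclusion of both ends of the second principal component, were chosen only after the result was seen.

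The difference between KO and WT cells in DIAM (1191 genes by edgeR) went with lower Schwann or neuronal markers, of which 7 of 9 were tested, 3 passed and 0 are in a gene list (camera adjusted p = 7.54e-05; adjusted p = 0.12 with an estimated correlation); Tubb3, which passed, was at 45.7 ± 12.4 CPM in WT and 21.3 ± 5.64 CPM in KO cells, and Sox10, which did not pass (adjusted p = 0.0839), at 45.7 ± 18.4 and 11.7 ± 6.88 CPM. In the model over all 16 libraries the other splits of these 8 libraries gave at most 0 genes over 35 splits. A share of 1 in 35 is the smallest that 35 splits allow, and it was not corrected over the comparisons. The real split also gave 0 when only the 8 libraries were fitted, so chance is not firmly excluded. Without any 1 library the called genes kept a median of at least 82.6% of their log2 fold change, the lowest being without WT library 2. That lies above the bound set beforehand against a single unusual library. The genes were called with all libraries, however, which favours genes steady across replicates, so this share cannot decide the question. The number of calls fell to 178 without KO library 2, 275 without KO library 1, 299 without WT library 1 and 316 without WT library 2. It was 16 without both WT library 2 and KO library 1. With the Schwann or neuronal score as a covariate, 0 genes passed edgeR's test (714 at an unadjusted p under 0.05; the covariate was not run with other tools), the 487 genes that rose kept a median of 54.6% of their log2 fold change (0.36 before and 0.19 after, with a median SE of 0.09 and 0.12) and the 704 that fell 50.9% (-0.54 and -0.24, SE 0.13 and 0.16). Those shares lie between the bounds set for and against an explanation by Schwann-like cells, with a covariate chosen after the data were seen. The score averages the 7 markers, and the 3 that passed are among the genes it is meant to explain. Tubb3 was at 68.7 ± 10.4 CPM (unscaled) in DMEM and 44.8 ± 12.2 CPM in DIAM in WT cells, whereas Sox10 rose. S100b, another of the 7, was at 4.62 ± 0.304 CPM (unscaled) in WT and 4.85 ± 0.597 CPM in KO cells in DIAM. The score may thus not follow Schwann-like cells alone. More such cells in the WT cultures may account for part of the difference. Genotype itself stays open as untested, because score and genotype go together in these 8 libraries.

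Mesothelial markers were uneven between replicates of a group. Upk3b, a uroplakin of mesothelial cells, was at 135 and 141 CPM in KO libraries 1 and 4 in DMEM and at 26.9 and 22.8 CPM in KO libraries 2 and 3, and in DIAM at 223 and 236 CPM in KO libraries 1 and 4 and at 69.9 and 63.6 CPM in KO libraries 2 and 3. The mean log2 level of the 8 mesothelial markers in DMEM correlated with that in the DIAM library of the same genotype and number (Pearson's r = 0.89, exact permutation p = 0.00238, adjusted p = 0.00714 over 3 relations; Spearman's rho = 0.881, p = 0.00724; n = 8 pairs), and r was 0.687 without KO libraries 1 and 4. The permutations mixed the genotypes, so a genotype difference in these markers would also enter r and p. Upk3b averaged 48 ± 17 CPM (unscaled) in WT and 81.3 ± 65.3 CPM in KO cells in DMEM, and 78.8 ± 38.4 and 148 ± 94.2 CPM in DIAM. A candidate explanation is that libraries of the same genotype and number came from 1 animal whose digest carried mesothelial cells. Over all genes the deviations of such pairs correlated at 0.12, -0.062, 0.22 and 0.15 for WT numbers 1 to 4. For KO numbers 1 to 4 they correlated at 0.29, 0.0024, 0.051 and 0.18, and 5 of the 8 pairs matched best with their own number. The Schwann or neuronal score gave no such relation (Pearson's r = 0.118, exact permutation p = 0.777, adjusted p = 0.777; Spearman's rho = -0.0238, p = 0.977; r = 0.209 without the pairs farthest from the median), and no biological explanation was tested.

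Arg1 counts were uneven among the DMEM libraries, from 2 to 49 in KO and from 3 to 4 in WT cells. Leukocytes carried along in the cultures are a candidate source. Between log2 Arg1 CPM and the leukocyte score Spearman's rho was 0.762 (exact permutation p = 0.0368, not adjusted over the 3 relations). Pearson's r was 0.575 (exact permutation p = 0.154, adjusted p = 0.232, n = 8 libraries). Without WT library 3 and KO library 2 Pearson's r was 0.387. With 8 libraries and these counts the explanation stays open, as does genotype.

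Other splits were also counted for the remaining comparisons. DIAM against DMEM gave 7839 genes in WT cells against at most 1 in the other splits, and 8623 in KO cells against at most 22, with 1 of 35 splits as large in each. That is the smallest share 35 splits allow, without correction over the 5 comparisons. Splits that mix the media also carry the medium's difference into the spread, which lowers their counts. The splits alone therefore do not firmly exclude chance, and the calls rest on edgeR's adjusted test. For KO against WT in DMEM 30 of 35 splits gave at least the 438 genes at an unadjusted p under 0.05, the highest other being 1786, so chance cannot be excluded, and a count several times the real one points to a structure of the samples, which was not identified. For the interaction 4 of 100 splits, the real one included, gave at least the 2255 genes at an unadjusted p under 0.05, the highest other being 3149. That share lies only just under 0.05, without correction over the 5 comparisons, and no gene passed the adjusted test, so chance is not firmly excluded.

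The response to DIAM differed between genotypes for 16 lists by camera on the interaction term, none of them with an estimated correlation (smallest adjusted p = 0.166). The median interaction log2 fold change was 0.28 for contractile, 0.66 for adipocyte, 0.70 for fatty acid synthesis, 0.26 for fatty acid oxidation, 0.12 for oxidative stress and 0.18 for insulin genes. It was -0.20 for matrix, -0.34 for protease, -0.33 for interferon, -0.49 for cell cycle, -0.12 for stress response and -0.43 for foam cell genes. Among markers it was -0.36 for leukocytes, 0.74 for perivascular adipocytes, -0.94 for Schwann or neuronal cells and 0.10 for mitochondrially encoded genes.

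In 34 of 662 groups of values (5.14%) 1 library lay apart from the 3 others by Dixon's test, where chance gives about 1 in 20 groups. That rate does not describe how the cases fell over the libraries, and WT library 2 in DIAM held the most. The same library lay at an end of the second principal component (43.19). Its chi-square per degree of freedom was 62.13 against WT library 3 and 57.82 against WT library 4 in DIAM, the largest between replicates. WT library 2 in DIAM was the one apart for Acta2 (522 CPM), Fads1 (163), Gclc (66.8), Gpnmb (980), Mmp13 (16.6), Tagln (329), Thbs1 (1080), Trib3 (21.3), Adrb3 (19.1), Gria1 (14.2), Synpo2 (8.03), Tnc (329) and the mean log2 CPM of the TGF-beta list (6.37). Other libraries in DIAM were WT library 3 for the leukocyte list (2.75 mean log2 CPM), KO library 4 for the cell cycle list (2.65 mean log2 CPM), Gclc (95.0 CPM) and Bub1 (1.51 CPM), KO library 3 for Cd9 (92.4 CPM), and KO library 1 for Rrm2 (56.7 CPM) and Nfkbia (57.2 CPM). In WT cells in DMEM they were library 4 for the cholesterol efflux list (6.03 mean log2 CPM), the interferon list (3.99 mean log2 CPM) and Mbp (9.03 CPM), library 3 for the matrix list (10.9 mean log2 CPM), library 2 for Cidec (0.413 CPM) and Timp4 (1.19 CPM), and library 1 for Fabp4 (64.8 CPM), Fads1 (247 CPM) and Hadhb (83.0 CPM). In KO cells in DMEM they were library 3 for Cd9 (180.0 CPM), library 2 for Fabp4 (50.0 CPM) and Sox10 (13.5 CPM), library 4 for Fam107a (0.239 CPM) and library 1 for Gbp2 (25.1 CPM).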

How the results depend on the processing

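DESeq2 on the same counts, limma on log2(CPM + 1), both marker scores as covariates and the exclusion of both ends of the second principal component (WT library 2 and KO library 1 in DIAM) were chosen only after the result was seen. The number of genes that differed between KO and WT cells in DIAM was 1191 and became 0 when only the 8 libraries compared were fitted (3674 at an unadjusted p under 0.05), 1884 with library weights, 167 with a log2 fold change of at least 1, 1810 in the authors' deposited table, 1873 with DESeq2, 0 with the Schwann or neuronal score as a covariate (714 unadjusted), 703 with the mesothelial score and 16 without both ends of the second component; it ran from 178 to 1480 when each library was left out, and from 890 to 1449 over the other settings. A log2 fold change of at least 1 left 2140 genes for DIAM in WT and 2432 in KO cells, and leaving out each library gave 7245 to 7805 and 8058 to 8306. KO against WT in DMEM gave 0 by edgeR, 2 in the authors' deposited table, 1 with DESeq2, and 0 to 2 without each library. The interaction gave 0 by edgeR, 1 with a pseudocount of 5, 234 in the authors' deposited table, 225 with DESeq2, and 0 to 1 without each library. Its genes at an unadjusted p under 0.05 went from 2255 to 532 with the Schwann or neuronal score as a covariate. The slope of the medium responses was 0.839 without a filter, in which the added genes of low count took part, and ran from 0.945 to 0.994 without each library. Of 100 tests of gene lists camera called 55, 2 with an estimated correlation, and 48 to 58 without each library. Apart from changes that follow from fewer libraries or a minimum fold, the cause was not tested.

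Of 306 values of named genes, 279 passed, 273 with a pseudocount of 0.1, 278 with median-ratio scaling and 277 with quantile normalization. In DIAM 65 of 85 named genes that passed lost their call between genotypes without at least 1 library, in KO cells Ulk1 lost its fall with DIAM without KO library 2 in DMEM, and no call in WT cells was lost. The log2 fold change of Acta2 between genotypes in DIAM, which did not pass, ran from -0.0184 without KO library 3 to 0.29 without KO library 4.

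The labels do not say that replicate numbers pair the libraries, and over all genes not every same-numbered pair correlated above 0.1, although the mesothelial markers did between media (r = 0.89). Same-numbered deviations correlated from -0.062 to 0.22 for DIAM in WT, 0.0024 to 0.29 in KO, -0.2 to 0.1 for genotype in DMEM and -0.18 to -0.015 in DIAM, and 5 of the 8 pairs between media correlated best with their own number. The replicate block was of genotype and number for the medium comparisons and the interaction, and of number alone for the genotype comparisons. A block of number alone joins KO and WT libraries, so it is not a block by animal. With these blocks the calls numbered 8008, 8775, 0, 1191 and, for the interaction, 0. The slope was 0.969, 58 list tests were called and 270 named values passed. Depth was 37221192 to 47626331 counts per library, and genes such as Arg1 were left out by the filter, not by depth.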

Other observations

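Of 12 fibroblast markers 10 rose and 2 fell with DIAM in each genotype, and 1 of each kind is given here, chosen after the values were seen. In KO cells Dcn rose from 474 ± 75.5 to 852 ± 36.7 CPM (mean ± SD, n = 4; adjusted p = 4.67e-05, edgeR). Lum, which encodes the matrix proteoglycan lumican, fell from 160.3 ± 6.85 to 44.2 ± 5.98 CPM in KO cells (adjusted p = 7.8e-06) and from 151 ± 25.5 to 56.3 ± 25.8 CPM in WT cells (adjusted p = 0.000111).

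Xist, the RNA that silences an X chromosome in female cells, was present in all 16 libraries although all are labelled male. It was at 161 ± 46.3 CPM (unscaled, n = 4) in WT and 231 ± 87.8 CPM in KO cells in DMEM, and at 128 ± 20 and 110 ± 8.33 CPM in DIAM. The 4 Y-linked genes of that marker list were not analysed here, so they give no check of the sex label.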
